A study of Mus musculus with 40 samples.

How the data were processed

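Total RNA from brains of postnatal day 9 C57/Bl6 mice had been extracted with a lipid tissue kit, labelled with biotin and hybridised to Affymetrix arrays. The 40 arrays formed 8 groups of 5. Per the labels, the Vehicle and IDR groups received vehicle or the peptide IDR-1018 10 h before the brains were removed, and the LPS group received lipopolysaccharide 6 h before removal. The LPS with IDR group received the peptide 4 h before LPS, with removal 6 h after LPS. In the LPS/HI groups, vehicle or peptide was given 4 h before LPS, hypoxia-ischaemia (HI) followed 14 h after LPS, and the left (injured) and right (uninjured) hemispheres were taken 6 h after HI. The labels do not say whether each array is a separate animal, nor the sex of the pups. The p-values therefore measure the spread between samples.

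The deposited values are RMA signals on the log2 scale, 1 per probe set and array, with no version given for RMA or the affy package named in the processing notes. RMA corrects the background, quantile normalises and summarises the probes, so a shift shared by all genes of an array would not be visible. The values ran from 1.84 to 14.0, and the array medians from 6.99 to 7.13. There were 34760 probe sets. Of these, 21640 carried 1 gene symbol, 1321 carried several and 11799 carried none. Symbols came from the probe annotation of the array, and 21553 probe sets had a gene ID found in the mouse RefSeq genes of assembly GRCm38.p6. No coordinates are given, because the array annotation names no build. Probe sets with 1 symbol were kept, and for the 954 genes with several probe sets the one with the highest mean over all arrays was taken. This left 19937 genes, with no filter on signal.

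Each pair of groups was compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the package data.table at version 1.17.8, using the arrays of the groups compared. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 19937 genes. There were 10 comparisons of 2 groups and 2 interactions, each a difference of 2 differences over 20 arrays. Errors of log2 fold changes are standard errors, and errors of group means are standard deviations. With 5 arrays per group, the median 95% half-width of a log2 fold change was between 0.15 and 0.18 in the comparisons of groups and 0.22 and 0.25 in the interactions. The number of arrays limits this precision. The procedure was tested on simulated data with the spread of each gene in each comparison. Of simulated differences of 0.5 on the log2 scale, 64.2% to 88.1% were called in the comparisons of groups and 56.7% to 59.7% in the interactions. Each simulation changed 67 genes by 0.3, 67 by 0.5 and 66 by 1 at once, with independent noise. With few changed genes the adjusted threshold is stricter, and a smaller share would be called.

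Gene lists were fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. The lists were cytokines and chemokines, NF-kB targets, acute phase genes, anti-inflammatory genes, interferon response, immediate early genes, heat shock, hypoxia response, unfolded protein and integrated stress, p53 and cell death, NRF2 antioxidant, glucocorticoid response, cholesterol synthesis, cell cycle, reactive astrocyte and activated endothelium. Marker lists covered microglia, neutrophils, monocytes, lymphocytes, astrocytes, the oligodendrocyte lineage, neurons, striatum, cerebellum, endothelium, choroid plexus and meninges with fibroblasts. A list of erythroid markers is not reported here, leaving 28 of 29 lists. Some genes stand in several lists, for example Lcn2 in the acute phase, reactive astrocyte and neutrophil lists. Each list was tested with limma's camera at its preset correlation of 0.01 between genes, and again with the correlation estimated for each list. List p-values were adjusted over the lists within a comparison. Member counts use the adjusted p over all genes, beside counts adjusted over the list alone.

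Of the called genes whose groups did not overlap (every array of one above every array of the other), those with the highest and lowest log2 fold changes were named. There were 10 in each direction for LPS against Vehicle and for the injured against the uninjured hemisphere without peptide, and 5 in each direction elsewhere. Where fewer than 3 genes passed, the 3 with the smallest p were named as not past the threshold. Clone names, Xist and Y-linked genes were passed over. For each list described, up to 4 called members were chosen by absolute fold change, or up to 2 by p where none was called. Nr4a3 was named outside this rule, after its values were seen.

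The number in the labels was checked as a possible pair by correlating each array's deviation from its group mean with that of the array of the same number in the other group. In the LPS/HI groups without peptide, the correlations for the 5 numbers were 0.493, 0.416, 0.412, 0.353 and 0.642, and each array correlated best with its own number. The numbers were read as pairing these hemispheres, and the value with a block for the number is given with the unblocked one where it changes a call or moves a count by over 1.5 times. In the other comparisons not all 5 correlations were over 0.1.

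The alternatives tried were the mean of all probe sets of a gene, a filter removing the 2485 genes with a mean under 5, 1 fit to all 8 groups, eBayes with trend and robust estimation, arrays centred on their median, array weights, the Xist level as covariate, the number as block, and leaving out each array in turn. Chosen after seeing the data were the mean level of 55 ribosomal protein genes as covariate, both LPS/HI arrays numbered 3 left out, the block together with an estimated correlation for the lists, simulated data that keep the hemispheres as pairs, and Xist with the Y-linked genes left out of the correlation between effects. The array numbered 5 of the LPS group, also doubted after the data were seen, had been left out in turn already. No array was left out of the values reported.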

Results

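Gene expression was measured in the brain of postnatal day 9 mice on 40 Affymetrix arrays, 5 for each of 8 groups. The groups tested the immunomodulatory peptide IDR-1018 (IDR) alone, lipopolysaccharide (LPS, a bacterial cell wall component that sensitises the neonatal brain) alone, both together, and both hemispheres of a model in which LPS is followed by hypoxia-ischaemia (LPS/HI), with and without the peptide. Array medians ran from 6.99 to 7.13 on the log2 scale. Correlations between arrays over the genes tested lay between 0.987 and 0.998, and no 2 arrays were identical. The first 2 principal components held 21.5% and 15.8% of the variance.

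The groups were unequal in sex-linked transcripts. Xist, the RNA that silences an X chromosome in females, was high with no Y-linked signal in 5 of 5 LPS arrays, 2 of 5 Vehicle arrays, 1 of 5 IDR arrays and 2 of 5 arrays of LPS with IDR. The remaining arrays of these groups had Y-linked signal and low Xist. Among LPS/HI arrays without peptide, 4 uninjured arrays had Xist alone and 1 had Y-linked signal alone. The injured arrays held 3 with Xist alone, 1 with Y-linked signal alone and 1 with both. With the peptide, 3 arrays had Xist and 2 had Y-linked signal in each hemisphere. The mean log2 level of 55 ribosomal protein genes also differed between arrays within groups, for example from 10.35 to 10.64 among the LPS arrays.

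LPS alone was compared with Vehicle to show the response of the brain to LPS after 6 h. Lcn2, which encodes the iron-binding acute phase protein lipocalin 2 (probe set 10481627), rose from 5.87 ± 0.20 to 9.77 ± 0.59 (mean log2 signal ± SD, n = 5 each). Its log2 fold change was 3.90 ± 0.22 (limma adjusted p = 6.96e-07), or 14.9-fold. The other genes with the highest fold changes were mostly interferon-induced. Iigp1, Irgm1, Gbp4 and Gbp5, guanosine triphosphatases of cell-autonomous defence, rose by 2.47 ± 0.15, 2.13 ± 0.11, 2.28 ± 0.14 and 2.00 ± 0.12. Ifit3, Ifit1, Ifitm3, Oasl2 and Trim30a, further interferon-inducible genes, rose by 1.87, 1.81, 1.81, 1.61 and 1.51. Among genes that fell were Tek, the endothelial angiopoietin receptor, at -0.85 ± 0.14, and Slc40a1, the iron exporter ferroportin, at -0.73 ± 0.10. Smaller decreases were seen for Cd180, a regulator of LPS signalling, at -0.57, Adgre5 at -0.57, and Tfrc, the transferrin receptor, at -0.53. Gpr34, a microglial receptor, was at -0.52, Gulp1 at -0.44, Nes (the progenitor filament nestin) at -0.43, Itga2 at -0.41 and Efhd1 at -0.39.

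Of 22 measured interferon response genes, 14 rose with LPS (18 adjusted over the list alone), and the list shifted upward (camera adjusted p = 3.98e-58, and adjusted p = 0.002 with an estimated correlation). Among glucocorticoid response genes, 5 of 12 rose (9 adjusted over the list alone), including Sult1a1 at 0.96 ± 0.11, Fkbp5, a co-chaperone of steroid receptors, at 0.62 ± 0.07, Zbtb16 at 0.54 and Tsc22d3 at 0.40. The list test gave an adjusted p of 1.56e-20, and 8.15e-04 with an estimated correlation. Acute phase genes rose in 6 of 18 cases, 10 adjusted over the list alone, with Saa3 at 0.99 ± 0.17, Steap4 at 0.74 and Cp (ceruloplasmin) at 0.55 beside Lcn2. Their list had an adjusted p of 1.83e-17, and 0.0076 with an estimated correlation. The reactive astrocyte list rose in 7 of 25 members (11 adjusted over the list alone; adjusted p = 4.34e-11, and 0.0027 with an estimated correlation). Its leading members Lcn2, Iigp1 and Cxcl10 also belong to other lists, and its median log2 fold change was 0.03 against a mean of 0.44.

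The metal-binding metallothioneins Mt2 and Mt1, at 1.19 ± 0.11 and 1.04 ± 0.16, were the 2 called members of the 13 NRF2 antioxidant genes (adjusted p = 0.003, and 0.0435 with an estimated correlation). Some other members hardly differed, such as Gclm at a mean log2 signal of 9.92 with LPS and 9.93 in Vehicle, and Nqo1 at 6.54 and 6.52. Slc7a11 was lower, at 9.72 against 10.28, so the shift was not shared by all members. The glucose transporter Slc2a1 rose by 0.56 ± 0.07 as the 1 called gene of 17 in the hypoxia response list (adjusted p = 2.05e-05, and 0.0076 with an estimated correlation). Lrg1 and the adhesion molecule Icam1, at 0.53 and 0.43, were the called genes of 10 in the activated endothelium list (adjusted p = 6.96e-04, and 0.0414 with an estimated correlation). Cytokines and chemokines rose in 4 of 22 cases (9 adjusted over the list alone), namely Cxcl10 at 1.5 ± 0.27, Il1a at 0.96, Ccl12 at 0.94 and Ccl19 at 0.57. Their list p was 1.29e-12, with an adjusted p = 0.0517 with an estimated correlation. The microglia list was mixed, with the complement genes C1qb at 0.48 and C1qa at 0.44 higher and Gpr34 lower (adjusted p = 7.81e-04, and adjusted p = 0.303 with an estimated correlation).

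Further lists passed at the preset correlation alone. NF-kB targets had 1 called gene, Ptgs2 (cyclooxygenase 2) at 0.88, with an adjusted p = 0.0551 with an estimated correlation. Upward shifts were also found for the astrocyte list, with Gjb6 at 0.62 and Fgfr3 at 0.51 (0.0674 as the adjusted p with an estimated correlation), the monocyte list with Ms4a6c at 0.98 (0.114), the neutrophil list with Lcn2 alone (0.195), the anti-inflammatory list with Il4ra at 0.52 (0.195) and the oligodendrocyte lineage with no called gene (0.165). Downward shifts were found for endothelial markers with Tek (adjusted p = 0.177 with an estimated correlation), and without called genes for cholesterol synthesis (0.328), cell cycle (0.265) and meninges with fibroblasts (0.195). Immediate early genes, heat shock, unfolded protein stress, p53 targets, and markers of lymphocytes, neurons, striatum, cerebellum and choroid plexus gave adjusted p-values between 0.147 and 0.949 and no called gene.

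In total, limma called 166 genes between LPS and Vehicle, 146 higher and 20 lower, of which 82 changed more than 1.5-fold. Groups did not overlap for 399 genes, or 2.00%, where chance gives 0.794%. All 5 LPS arrays carried Xist against 2 of the Vehicle arrays. With the Xist level as covariate 86 genes passed, 83 of them among the 166, and of the 10 named genes that fell only Cd180 still passed.

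**Figure D1:**
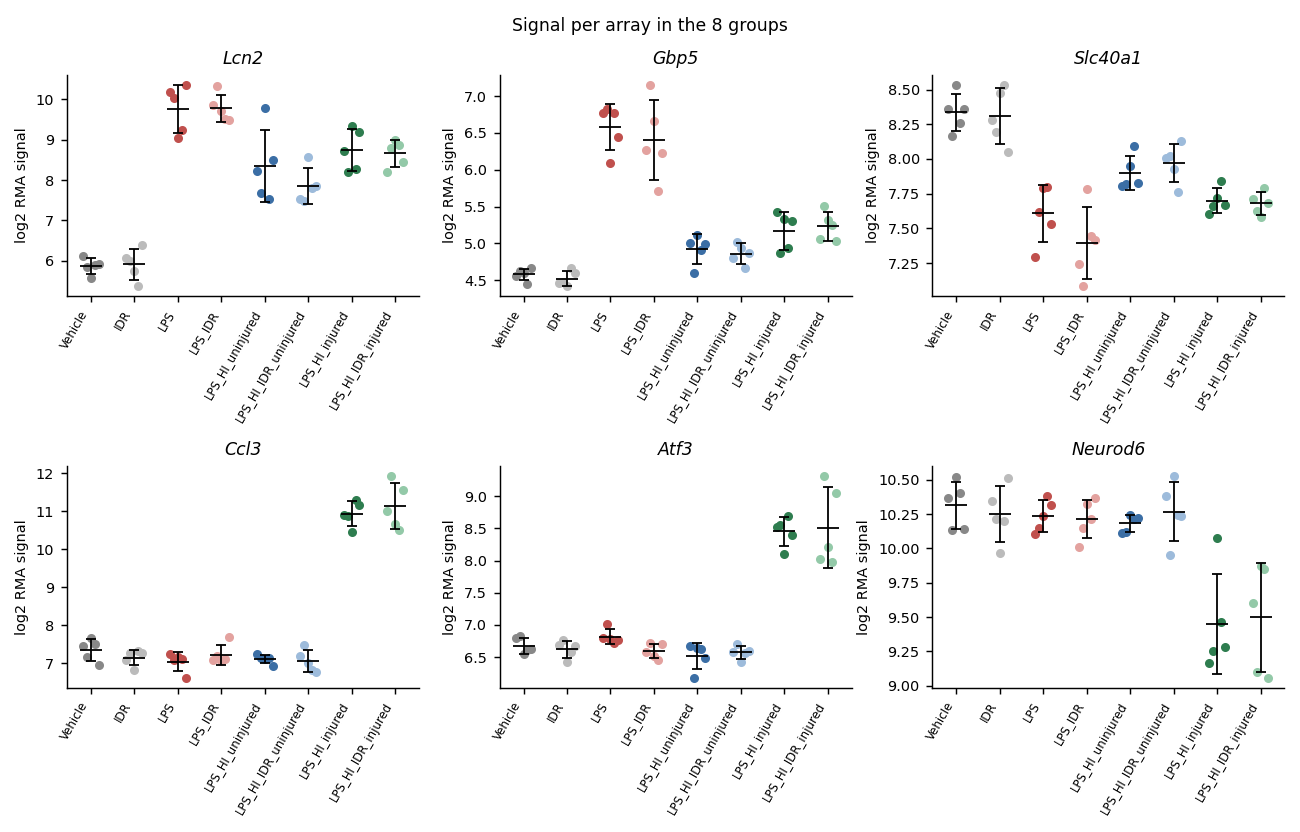
Log2 RMA signal of 6 genes in the 8 groups. Each point is an array and each bar with its whisker the mean and SD of 5 arrays. Lcn2 lay near 5.87 in Vehicle and 9.77 with LPS, and Ccl3 was high in both sets of injured hemispheres, with means of 10.94 and 11.13.

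The peptide alone was compared with Vehicle 10 h after dosing. Levels of the genes that LPS changed were close in both groups, for example Lcn2 at 5.91 ± 0.38 with IDR and 5.87 ± 0.20 with Vehicle, and Iigp1 at 4.89 ± 0.21 and 4.95 ± 0.19 (n = 5 each). The genes with the smallest p were Zfp442, a zinc finger gene, at -0.51 ± 0.10, Efcab9 at -0.31 ± 0.06 and the olfactory receptor gene Olfr338 at 0.36 ± 0.08, each with an adjusted p of 1.00. Cholesterol synthesis and cell cycle lists shifted downward with median log2 fold changes of -0.07 and -0.08 (camera adjusted p = 0.0405 for both). Each had an adjusted p = 0.825 with an estimated correlation, and none of their genes was called. limma called 0 genes, with 321 at an unadjusted p under 0.05 where 997 would be expected by chance. The median 95% half-width was 0.16 on the log2 scale, and of simulated differences of 0.5 and 0.3, 80.6% and 44.8% were called. These shares hold with many genes changed at once and would be lower with few.

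The peptide before LPS was compared with LPS alone, the question being whether it alters the LPS response. Lcn2 was at 9.78 ± 0.34 with the peptide and 9.77 ± 0.59 without, Iigp1 at 7.38 ± 0.76 and 7.42 ± 0.37, and Gbp5 at 6.4 ± 0.54 and 6.58 ± 0.32 (n = 5 each). Ifit3 at 8.69 ± 0.67 and 8.15 ± 0.38, Ifit1 at 8.12 ± 0.62 and 7.64 ± 0.20, and Trim30a at 8.64 ± 0.35 and 8.14 ± 0.12 had higher means with the peptide, and Gbp4 at 7.91 ± 0.88 and 8.31 ± 0.36 a lower one, none of them called (limma adjusted p of 0.326 to 0.591). C1qtnf9, a secreted relative of adiponectin, had the smallest p, at -0.40 ± 0.05 (limma adjusted p = 0.0904). Eef2k, the kinase of elongation factor 2, was at 0.48 ± 0.08 (adjusted p = 0.203, with 0.02 at its other probe set) and Tex24 at -0.44 ± 0.07 (adjusted p = 0.258). Microglia markers shifted downward with a median of -0.16, none called over all genes and 5 of 17 adjusted over the list alone (camera adjusted p = 8.68e-04, and adjusted p = 0.942 with an estimated correlation). The microglial genes with the smallest p were Laptm5 at -0.33 and Cd68 at -0.24. The oligodendrocyte lineage had a median of -0.21 and no called gene (adjusted p = 0.0027, and adjusted p = 0.942 with an estimated correlation). limma called 0 genes, while 2674 had an unadjusted p under 0.05 against 997 expected. The arrays of LPS with IDR had a mean ribosomal protein level 0.11 lower on the log2 scale, and 3 of them had Y-linked signal where no LPS array had. The label of the LPS group does not say that vehicle was given before LPS.

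The LPS effect in pups given the peptide was measured as LPS with IDR against IDR alone. Lcn2 rose by 3.87 ± 0.18 (adjusted p = 1.81e-07), Ifit3 by 2.49 ± 0.24, Iigp1 by 2.49 ± 0.28, Ifit1 by 2.19 ± 0.27 and Irgm1 by 2.13 ± 0.17. Slc40a1 at -0.92 ± 0.12, Slc16a4, a monocarboxylate transporter, at -0.88, Adgre5 at -0.73, the apelin receptor Aplnr at -0.70 and the vascular growth factor receptor Kdr at -0.63 were lower. Interferon response genes rose in 15 of 22 cases (18 adjusted over the list alone; camera adjusted p = 1.20e-38, and 0.0145 with an estimated correlation). Glucocorticoid response genes rose in 8 of 12 cases, with Fkbp5 at 0.92 ± 0.08 and Pdk4 at 0.64 ± 0.10 (10 adjusted over the list alone; 3.65e-20, and 0.0145 with an estimated correlation). The acute phase, hypoxia and reactive astrocyte lists also passed both tests, with 8 of 18, 2 of 17 and 6 of 25 genes called. Among endothelial markers Tek at -0.80, Kdr and Tie1 at -0.29 were lower (adjusted p = 0.0027, and adjusted p = 0.274 with an estimated correlation). Of microglia markers, P2ry12 at -0.47, Gpr34 at -0.56 and Siglech at -0.36 were lower and C1qb at 0.45 was higher (adjusted p = 0.715).

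limma called 294 genes here, 232 higher and 62 lower, with 682 genes (3.42%) not overlapping between groups against 0.794% by chance. Of the 146 genes higher with LPS alone, 123 were also higher in pups given the peptide where independent calls would share 1.70, and 11 of the 20 lower ones were also lower. None was called in opposite directions. The difference of the 2 LPS effects was tested as an interaction, which called 1 gene. Tex24 (probe set 10571167), named for expression in testis, had an interaction of -0.63 ± 0.09 (limma adjusted p = 0.0146). Its mean log2 signal was low in every group, 4.32 ± 0.06 in Vehicle, 4.51 ± 0.08 with IDR, 4.65 ± 0.16 with LPS and 4.21 ± 0.05 with both. Zfp442 at 0.62 ± 0.14 and Clca3a1 at 0.47 ± 0.10 did not pass (adjusted p = 0.860 each). Lists of immediate early genes, microglia and oligodendrocyte lineage had lower interactions at the preset correlation (adjusted p = 0.0167 each), with adjusted p-values of 0.934 to 0.940 with an estimated correlation. The Tex24 call was lost in the fit to all 8 groups, with the filter on low signal, and without Vehicle replicate 4, IDR replicate 1 or LPS with IDR replicate 1. Without LPS replicate 2 the interaction called 2 genes.

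**Figure D2:**
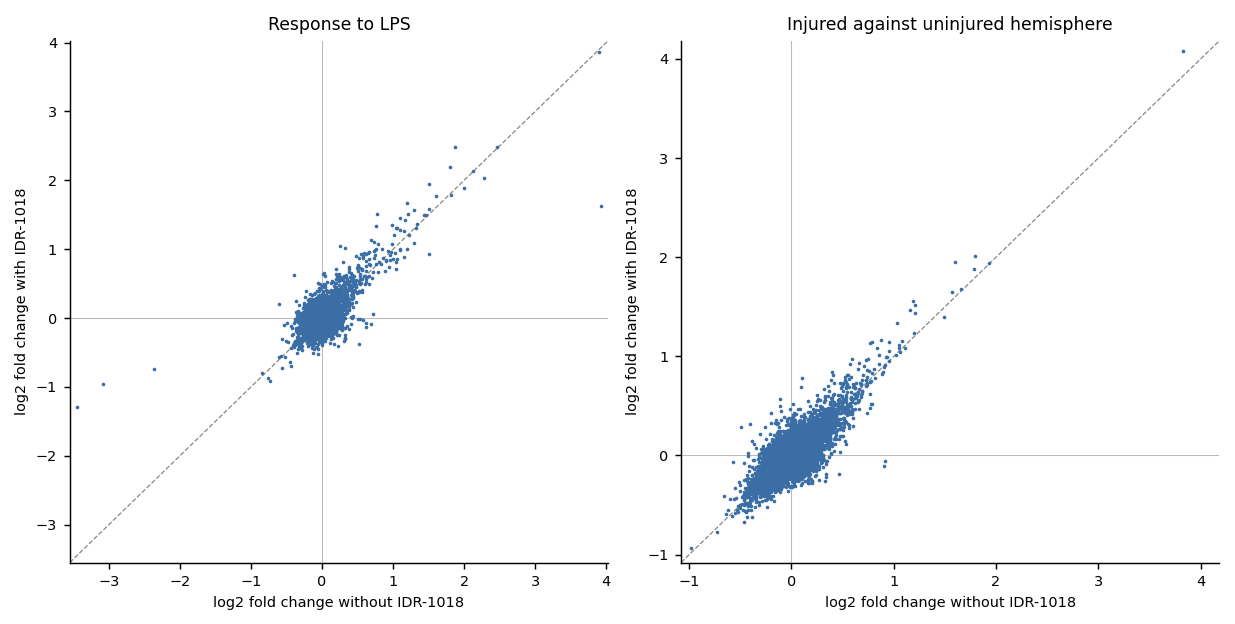
Log2 fold change of each gene without the peptide (horizontal axis) and with it (vertical axis), for LPS and for the injured hemisphere. Each point is a gene and the dashed line marks equal effects. The across-gene correlation, without Xist and the Y-linked genes, was 0.527 for LPS and 0.779 for injury. Points far from the line in the LPS panel are Xist and Y-linked genes, in which the groups differ in composition.

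The injured hemisphere was compared with the uninjured one 6 h after HI to show the response to injury. The chemokine gene Ccl3 (probe set 10389231) rose from 7.11 ± 0.11 to 10.94 ± 0.33 (log2 signal, SD, n = 5 each), a log2 fold change of 3.83 ± 0.13 (limma adjusted p = 1.24e-09). Atf3, a stress-induced transcription factor, rose by 1.93 ± 0.12, the inducible heat shock protein gene Hspa1a by 1.80 ± 0.28 and the membrane protein gene Emp1 by 1.79 ± 0.12. Chemokines Ccl2 and Ccl9 rose by 1.65 ± 0.09 and 1.57 ± 0.13, and the myeloid receptor gene Lilrb4a by 1.6 ± 0.13. Gadd45b, Gem and the LPS co-receptor gene Cd14 rose by 1.49, 1.21 and 1.2. Among genes that fell, Neurod6, a transcription factor of cortical neurons, was lower by 0.73, the protocadherin gene Pcdh20 by 0.66, Tafa1 by 0.62, Brinp3 by 0.60 and the serotonin receptor gene Htr2a by 0.58. Ankrd34c, Hs3st5, Pth2r, Car4 and the deiodinase gene Dio2 fell by 0.57, 0.55, 0.54, 0.53 and 0.64.

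Cytokines and chemokines rose in 12 of 22 cases in the injured hemisphere (15 adjusted over the list alone; camera adjusted p = 2.65e-20, and 0.0156 with an estimated correlation). Reactive astrocyte genes rose in 14 of 25 cases, among them Osmr, the oncostatin M receptor, at 1.06 ± 0.12 (20 adjusted over the list alone; 9.89e-25, and 0.0095 with an estimated correlation). The p53 and cell death list had 6 of 16 genes higher, with Gadd45g at 0.89, Tnfrsf12a at 0.73 and Phlda3 at 0.62 (9 adjusted over the list alone; 4.01e-09, and 0.0072 with an estimated correlation). With the number as block, these lists no longer passed with an estimated correlation. The camera adjusted p was then 0.158 for cytokines and chemokines and 0.0583 for the reactive astrocyte and p53 lists. Stress lists rose too. Of 17 hypoxia genes 5 were higher, led by haem oxygenase Hmox1 at 1.19 ± 0.13 and Adm (adrenomedullin) at 0.61 ± 0.15 (estimated-correlation adjusted p = 0.0262). Of 17 unfolded protein and integrated stress genes 5 were higher, including Atf4 at 0.58 and Ddit3 at 0.43 (0.0291). NRF2 antioxidant genes were higher in 3 of 13 cases (0.0219), acute phase genes in 4 of 18 (0.0315) and NF-kB targets in 2 of 17, Tlr2 at 0.58 and Tnfaip2 at 0.35 (0.0291). With the block the estimated-correlation adjusted p was 0.158 for unfolded protein stress. It was 0.0924 for the hypoxia, NRF2, acute phase and NF-kB lists, so none of them passed. Neuron markers fell as a list with Neurod6 the 1 called gene of 18, and striatum markers with Gpr6 at -0.44 the 1 of 8 (both 0.0219). With the block these became 0.146 and 0.0924, so neither list passed.

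Other lists passed at the preset correlation alone in the injured hemisphere. Heat shock genes rose in 3 of 14 cases, Hspa1a, Hsph1 at 0.57 and Bag3 at 0.54 (adjusted p = 0.0605 with an estimated correlation). Interferon response genes rose in 2 of 22 cases, Ifit3 at 0.83 and Rsad2 at 0.57 (also 0.0605). Activated endothelium rose with Icam1, Esm1 and Sele (0.122) and the anti-inflammatory list with Il1r2, Socs3, Il1rn and Il4ra (0.151). Cholesterol synthesis and cell cycle shifted downward (0.068 and 0.582), with Nsdhl at -0.40 called. Immediate early genes did not shift as a list (adjusted p = 0.193), with 5 members called higher, among them Fos at 0.77, Fosb at 0.70 and Maff at 0.50 beside Atf3, and 1 called lower, Nr4a3 at -0.36. P2ry12, a receptor of resting microglia, fell by 0.45 while the microglia list did not shift (adjusted p = 0.890).

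Between the hemispheres without peptide, limma called 596 genes, 434 higher and 162 lower in the injured one, 100 of them changed more than 1.5-fold. Groups did not overlap for 1003 genes (5.03%), where chance gives 0.794%. With the number in the labels as block, which pairs the hemispheres, 2032 genes were called, 1256 higher and 776 lower, the 596 among them. Called members went from 2 to 8 for NF-kB targets, 2 to 7 for interferon response, 3 to 7 for heat shock, 3 to 5 for activated endothelium, 1 to 4 for cholesterol synthesis, 1 to 7 for neuron and 1 to 4 for striatum markers. Among lists that did not shift, immediate early genes went from 5 higher and 1 lower to 6 and 4, microglia markers from 0 and 1 to 3 and 2, and glucocorticoid response genes from 1 and 0 to 3 and 1, and the other lists gained at most 2 in either direction except reactive astrocyte genes, which went from 14 to 20 higher. With the block and an estimated correlation, 0 of the 10 lists that had passed both tests did so (adjusted p of 0.0583 to 0.158). At the preset correlation these 10 lists still passed with the block (camera adjusted p of 5.58e-22 to 9.21e-04). The block leaves fewer degrees of freedom, so the loss does not show that the lists did not shift. With arrays centred on their median, 303 of 503 called genes were higher. The count was 1431 with 1 fit to all 8 groups, 1447 with array weights and 1640 with the ribosomal protein level as covariate. It fell to 285, 293 and 377 without injured replicate 1, 2 or 4, and to 364, 365 and 301 without uninjured replicate 1, 2 or 4. Injured replicate 3 carried both Xist and Y-linked signal, and leaving out both arrays numbered 3 gave 558 genes.

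The same comparison of hemispheres was made in pups given the peptide. Ccl3 rose by 4.08 ± 0.24 (limma adjusted p = 1.92e-06), Hspa1a by 2.02 ± 0.39, Lilrb4a by 1.95 ± 0.12, Atf3 by 1.94 ± 0.22 and Emp1 by 1.88 ± 0.11. Neurod6 fell by 0.77, the synapse gene Syndig1 by 0.62, Spink8 by 0.62, Htr2a by 0.61 and Hs3st5 by 0.58. Reactive astrocyte genes rose in 15 of 25 cases, with Timp1 at 1.17 ± 0.12 and Hspb1 at 1.15 ± 0.11 (20 adjusted over the list alone; camera adjusted p = 4.80e-29, and 0.0101 with an estimated correlation). Cytokines and chemokines rose in 12 of 22 cases (13 adjusted over the list alone; 6.23e-17, and 0.0284 with an estimated correlation). Striatum markers fell in 3 of 8 cases, with Gpr6 at -0.57, the phosphodiesterase Pde10a at -0.44 and the opioid precursor Penk at -0.37 (7 adjusted over the list alone; 1.89e-09, and 0.0203 with an estimated correlation). Monocyte markers rose with Thbs1 at 0.60 the 1 called gene of 12 (0.0033, and 0.0483 with an estimated correlation). The p53, unfolded protein stress, NRF2, acute phase and neuron lists also passed both tests, with 6 of 16, 6 of 17, 2 of 13 and 4 of 18 genes higher and 1 of 18 lower.

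With the peptide, limma called 498 genes between the hemispheres, 358 higher and 140 lower, and 1021 genes (5.12%) did not overlap against 0.794% by chance. Centring the arrays gave 256 higher of 481. A block for the number, given below because the pairing of these arrays stays open, also raised the count. The count was 1432 with all 8 groups in 1 fit, 854 with array weights, 1085 with Xist and 2082 with the ribosomal protein level as covariate. It fell to 279, 323 and 266 without injured replicate 1, 2 or 5, and to 230, 318 and 311 without uninjured replicate 1, 3 or 5. Of the 434 genes higher without peptide, 240 were also higher with it where independent calls would share 7.79, and 73 of the 162 lower ones were also lower against 1.14. None was called in opposite directions. The difference of the 2 injury effects was tested as an interaction, which called 0 genes with limma, 361 having an unadjusted p under 0.05 against 997 expected. Its genes with the smallest p were Olfr1090 at -0.43 ± 0.09, Asb4 at 0.68 ± 0.16 and Pgr15l at 0.68 ± 0.18, each with an adjusted p of 1. The list with the smallest p was meninges and fibroblasts (median 0.12, adjusted p = 0.0029, and adjusted p = 0.453 with an estimated correlation).

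**Figure D3:**
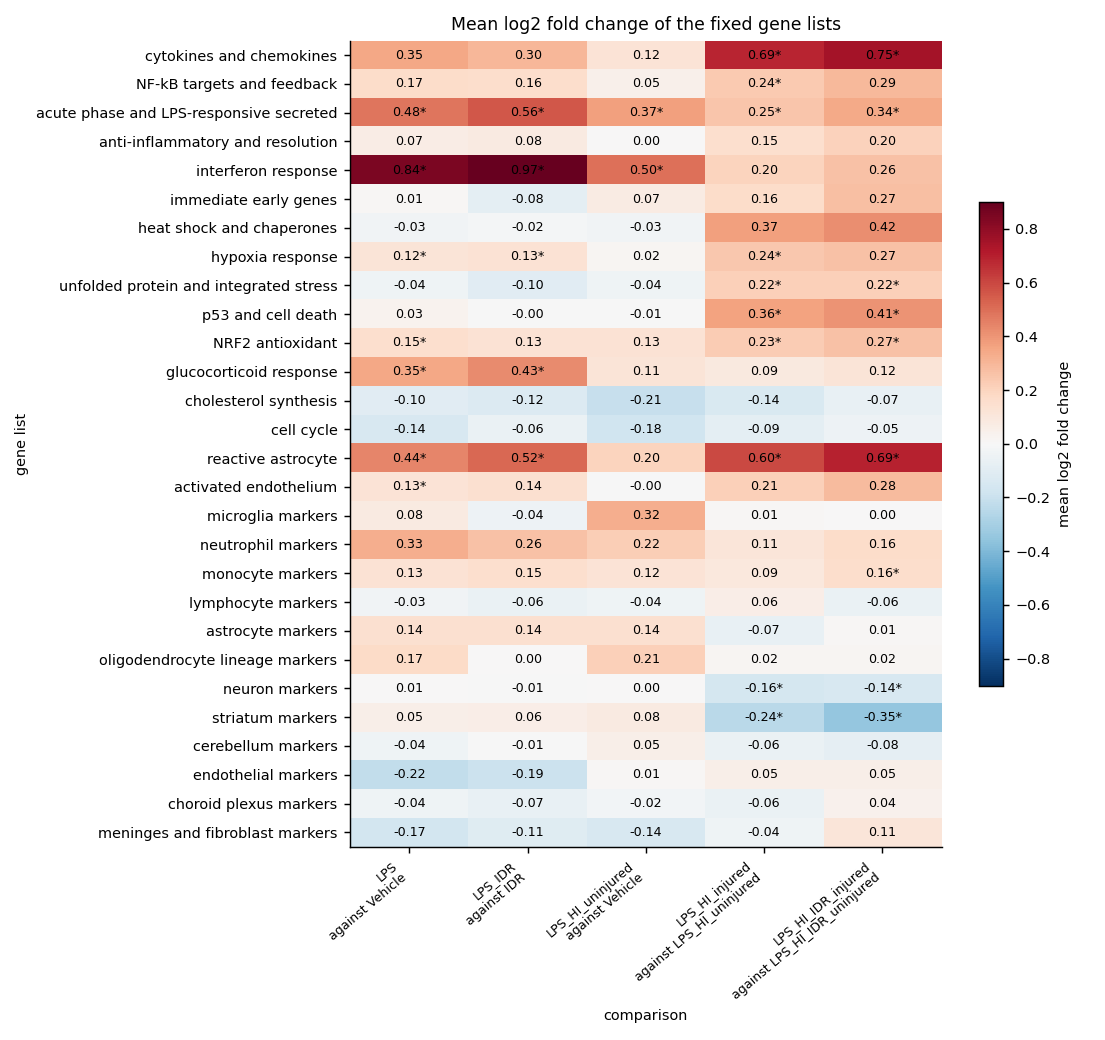
Mean log2 fold change over the members of each of 28 gene lists in 5 comparisons, as a heat map. A star marks an adjusted p under 0.05 with an estimated correlation and no block. Stars stand on 7 lists for LPS and 5 for LPS in pups given the peptide, on 2 lists for the uninjured hemisphere, and on 10 and 9 lists for injury without and with the peptide.

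Injured hemispheres with the peptide were compared with injured hemispheres without it, the comparison closest to the question of neuroprotection. Ccl3 was at 11.13 ± 0.60 with the peptide and 10.94 ± 0.33 without, Ccl2 at 8.02 ± 0.47 and 8.00 ± 0.13, Atf3 at 8.51 ± 0.62 and 8.45 ± 0.22, and Neurod6 at 9.5 ± 0.40 and 9.45 ± 0.36 (n = 5 each). Barhl1, a homeobox gene of cerebellar granule cells, at -0.32 ± 0.08, Bcl2a1c at -0.27 ± 0.07 and the interferon-inducible Ifi213 at -0.37 ± 0.10 had the smallest p, each with an adjusted p of 1. Interferon response genes shifted downward with a median of -0.11 (camera adjusted p = 4.13e-07, and adjusted p = 0.374 with an estimated correlation), Zbp1 at -0.23 and Gbp3 at -0.26 having the smallest p. Immediate early genes shifted upward with a median of 0.18 (6.48e-08, and adjusted p = 0.541 with an estimated correlation). Cell cycle genes and striatum markers shifted downward with medians of -0.14 and -0.08 (adjusted p = 0.420 and 0.232 with an estimated correlation). In total, 5 lists shifted upward and 5 downward at the preset correlation, and 0 passed with an estimated correlation. No member of these lists was called. limma called 0 genes, with 277 at an unadjusted p under 0.05 against 997 expected. The median 95% half-width was 0.18, and of simulated differences of 0.5 and 0.3, 76.1% and 28.4% were called. As above, these shares would be lower with few genes changed.

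The peptide was also compared with no peptide in the uninjured hemisphere. Ifi207, an interferon-inducible gene, was at -0.56 ± 0.13, Pgr15l, a G protein-coupled receptor gene, at -0.48 ± 0.10 and Olfr720 at 0.31 ± 0.07, each with a limma adjusted p of 1. Interferon response genes shifted downward with a median of -0.18 (camera adjusted p = 5.05e-14, and adjusted p = 0.142 with an estimated correlation), Usp18 at -0.27 and Zbp1 at -0.17 having the smallest p. Cell cycle genes had a median of -0.18, with Aurka at -0.16 and Cenpf at -0.20 (2.44e-12, and adjusted p = 0.283 with an estimated correlation). Cerebellum markers were lower with Zic2 at -0.25 and Zic1 at -0.30 (6.42e-05, and adjusted p = 0.361 with an estimated correlation). limma called 0 genes, with 376 at an unadjusted p under 0.05 against 997 expected.

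Uninjured LPS/HI hemispheres were compared with Vehicle. The groups differ in LPS, in the HI that the pups underwent, in handling and in the time from dosing to removal. They also differ in the tissue taken, 1 hemisphere against brain. Lcn2 rose by 2.47 ± 0.31 (limma adjusted p = 0.0016), Ifitm3 by 1.56 ± 0.21, Ifi207 by 1.49 ± 0.14, Rtp4 by 1.46 ± 0.10 and Saa3, a serum amyloid gene, by 1.36 ± 0.23. The matrix gene Tnc at -0.52, Aplnr at -0.51, Slc40a1 at -0.44, Itga2 at -0.38 and Ccdc80 at -0.31 were lower. Interferon response genes rose in 9 of 22 cases (17 adjusted over the list alone; camera adjusted p = 1.01e-41, and 0.0025 with an estimated correlation). Acute phase genes rose in 6 of 18 cases (8 adjusted over the list alone; 5.89e-12, and 0.0355 with an estimated correlation). Microglia markers rose in 6 of 17 cases, with C1qb at 0.88 ± 0.11, the protease Ctss at 0.87 ± 0.11 and Itgam at 0.71 ± 0.09 (8 adjusted over the list alone; 7.69e-19, and adjusted p = 0.0554 with an estimated correlation). limma called 87 genes, 82 higher and 5 lower, with 351 genes (1.76%) not overlapping against 0.794% by chance. The count was 276 with array weights, 143 with the ribosomal protein level and 53 with the Xist level as covariate, where none of the 5 named lower genes passed, and 51 without Vehicle replicate 4. Xist was high in 4 of these uninjured arrays against 2 of the Vehicle arrays.

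Injured hemispheres were also compared with Vehicle. These groups too differ in LPS, HI, handling, the time from dosing to removal and the tissue taken, whose effects cannot be told apart here. Among the genes that differed were some that had changed with LPS and some that had changed between the hemispheres. Ccl3 rose by 3.59 ± 0.15 (limma adjusted p = 2.44e-08), Lcn2 by 2.87 ± 0.19, Ifi207 by 2.08 ± 0.14, Ccl2 by 1.87 ± 0.09 and Lilrb4a by 1.86 ± 0.10. Neurod6 fell by 0.86, the microglial receptor gene P2ry13 by 0.86, Hs3st5 by 0.80, Hmcn1 by 0.78 (its 77 probe sets gave log2 fold changes of -0.88 to -0.03) and Opn3 by 0.74. Reactive astrocyte genes rose in 21 of 25 cases (23 adjusted over the list alone; camera adjusted p = 1.77e-31, and 0.0013 with an estimated correlation). Interferon response genes rose in 18 of 22 cases, also 18 adjusted over the list alone (5.14e-24, and 0.0015 with an estimated correlation). Cholesterol synthesis genes fell in 8 of 13 cases, with the pathway enzymes Mvd at -0.63 ± 0.10, Nsdhl at -0.61 ± 0.07 and Sqle at -0.48 ± 0.07 (10 adjusted over the list alone; 1.40e-09, and adjusted p = 0.0571 with an estimated correlation). Microglia markers rose in 10 of 17 cases and fell in 1, with C1qb at 0.96 and Itgam at 0.89 (3.31e-07, and adjusted p = 0.117 with an estimated correlation). In the oligodendrocyte lineage the myelin genes Mbp at 0.44 and Mal at 0.44 rose, and the progenitor markers Pdgfra at -0.32 and Cspg4 at -0.22 fell (0.014, and adjusted p = 0.355 with an estimated correlation). limma called 1663 genes, 887 higher and 776 lower, with 1743 genes (8.74%) not overlapping against 0.794% by chance. The count was 3210 with array weights and 917 with the Xist level as covariate, and 964, 1088 and 1034 without Vehicle replicate 1, 3 or 4.

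Whether the peptide opposes the effects of LPS or injury was examined as a correlation across genes, which are not independent replicates. Log2 fold changes of LPS with IDR against LPS correlated with those of LPS against Vehicle at r = -0.374. Both comparisons use the same LPS arrays, and simulated data with no effect gave a mean r of -0.520 (range -0.804 to 0.0374). The simulated data held no LPS effect either, and a real one draws r toward 0, so these r values are not like for like. The covariance was -0.006 against a simulated mean of -0.0047 (range -0.0143 to 1.8e-04). Without Xist and the Y-linked genes the covariance was -0.0039 against -0.0041. With the LPS arrays split so that each comparison used different ones, the mean r was -0.0898 over 20 splits (range -0.267 to 0.128), and 0.0169 without Xist and the Y-linked genes (range -0.1695 to 0.2451). For injury, the peptide in the injured hemisphere against the injury effect gave r = -0.241, against -0.496 in simulated data that draw the arrays singly. These simulated data held no injury effect either. The covariance was -0.0026 against a simulated mean of -0.0055 (range -0.0193 to 0.0032). The split gave a mean r of 0.132 (range -0.0113 to 0.287), and 0.117 without those genes. With the hemispheres kept as pairs, simulated data with no effect gave a mean r of -0.291 (range -0.606 to 0.0981), and 0.182 for the split (range -0.371 to 0.793).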

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

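The tests of the array with both sex markers were chosen after its values were seen, as were the genes Gh, Prl and Gabra6 and the covariate of ribosomal protein level. For the other explanations tested here the bounds were set before their tests were run. The sex composition, the ribosomal protein level and the excess of genes at an unadjusted p under 0.05 were themselves patterns seen in the data.

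Injured replicate 3 of the LPS/HI group without peptide carried Xist at 11.23 and a Y-linked mean of 8.01 on the log2 scale (Eif2s3y 8.69, Kdm5d 7.53, Uty 7.80), where each other array had 1 of these signals. A pup whose cells carry both an active Xist gene and a Y chromosome would have a full Y-linked level, but the linear share of the male level was 0.467 against at least 0.790 in the 16 arrays with Y-linked signal alone, which argues against it. RNA of a male and a female pup in 1 sample would give shares of Xist and Y-linked level that add up to about 1. The sum was 1.03, with an Xist share of 0.564, and other arrays gave sums of 0.748 to 1.24. A mixed sample is therefore a candidate explanation, and the uninjured array of the same number had Xist at 11.63 and a Y-linked mean of 4.27.

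Between LPS with IDR and LPS alone, 2674 genes had an unadjusted p under 0.05 where 997 would be expected, although none passed the adjustment. Sex composition, estimated from Xist-positive and Y-linked arrays within the other 6 groups, predicted the direction of a share of 0.343 of these genes. The r over them was -0.297. In some of those groups the 2 kinds of array also differed in ribosomal protein level. Among injured LPS/HI hemispheres with IDR it was 10.35 to 10.38 with Xist and 10.67 to 10.70 with Y-linked signal. This prediction therefore does not separate sex from that level and does not decide about sex. With the Xist level as covariate 1612 genes remained. The ribosomal protein level, with slopes from the same 6 groups, predicted the direction of a share of 0.910 (2429 of 2670 genes, r = 0.792) with a median predicted size of 0.415 of the measured one, and with this level as covariate 930 genes remained under 0.05. An axis of arrays that moves with ribosomal protein genes may therefore account for part of the excess, and whether it is technical or biological was not tested. Other splits of the 10 arrays gave up to 4198 such genes, and chance could not be excluded (5 of 100 splits had as many).

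All LPS arrays carried Xist, against 2 of 5 Vehicle arrays, so sex could contribute to the 166 genes called between them. The difference that the sex markers predict from the other 6 groups was a median of 0.0486 of the measured one over these genes. This argues against sex as the cause of the set, although the prediction may also carry the ribosomal protein level. Of the 166 genes, 164 had the same direction in LPS with IDR against IDR. Xist arrays were 2 of 5 and 1 of 5 there, also more with LPS, so this agreement alone does not separate sex from LPS. With Xist as covariate 86 genes passed. The median absolute log2 fold change of the 166 was 0.58 before and 0.59 after, while its median SE went from 0.08 to 0.11. Over the set the errors therefore widened while the changes did not shrink. The 20 lower genes were not examined apart from the 146 higher ones. Other splits of these arrays called at most 4 genes, so chance can be excluded.

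Some samples stood apart from the other 4 of their group by Dixon's test at a critical value of 0.71, which chance passes in about 1 of 20 groups. For gene lists 16 of 224 tests did so, where 11.2 are expected, and for named genes 4 of 190, where 9.5 are expected. Injured replicate 2 of LPS/HI with IDR was high for the mean log2 level of cytokines and chemokines (7.24), NF-kB targets (7.68) and acute phase genes (6.81), and for Lilrb4a (8.28). Uninjured replicate 2 of the same treatment was high for hypoxia response (9.14) and lymphocyte markers (5.56), and injured replicate 1 was low for neuron markers (10.95). In LPS/HI without peptide, injured replicate 1 was high for interferon response (7.52), injured replicate 2 low for cell cycle (7.10), injured replicate 3 low for Htr2a (9.02), and uninjured replicate 1 high for choroid plexus markers (8.16). IDR replicate 4 was low for cytokines and chemokines (5.87) and high for neuron markers (11.17). Vehicle replicate 5 was high for oligodendrocyte lineage markers (9.44) and ribosomal protein genes (10.54) and low for Tek (8.30). LPS replicate 1 was low for heat shock genes (10.07) and high for monocyte markers (6.42) and Tex24 (4.93), LPS replicate 5 was high for striatum markers (10.02), and LPS replicate 2 had a low array median over the genes tested (7.68). Array medians and ribosomal means gave 2 of 16 such results where 0.8 are expected.

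Hormone and cerebellar genes, picked after their values were seen, gave 6 of 24 such results. LPS replicate 5 had the pituitary hormone genes Gh at 10.85 and Prl at 6.28, against at most 6.43 and 4.71 in the other LPS arrays. Gh was also high in injured replicate 5 of LPS/HI with IDR (8.07) and IDR replicate 3 (6.80) and low in uninjured replicate 3 of LPS/HI with IDR (6.06). Injured replicate 5 of LPS/HI had Gabra6, a gene of cerebellar granule cells, at 7.09 against at most 4.91 in the others, and a mean of cerebellum markers of 8.58. The difference between groups that passed a test was the Tex24 interaction of peptide and LPS at -0.63.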

How the results depend on the processing

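The covariate of ribosomal protein level, the omission of both LPS/HI arrays numbered 3, the block with an estimated correlation, the simulated data with pairs and the correlation without Xist and Y-linked genes were chosen after seeing the data. Counts of called genes stayed within 1.5 times in 98 of 115 tests of settings other than leaving out an array. Named genes that had been called kept their direction in all settings. In the settings other than leaving out an array, 27 of 934 tests of named genes no longer passed, 14 of them with Xist as covariate. Of 3220 list tests in these settings 54 newly passed and 69 no longer did. Leaving out 1 array moved 20 of 140 counts by more than 1.5 times or to or from 0, and 83 of 1040 tests of named genes and 176 of 3920 list tests no longer passed. All these totals include comparisons that stayed at 0 called genes, and genes and lists that had not passed and so could not stop passing. Among results that could change, the share that did is therefore larger.

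With the Xist level as covariate, called genes went from 166 to 86 for LPS against Vehicle, from 87 to 53 for uninjured LPS/HI and from 1663 to 917 for injured LPS/HI against Vehicle, and from 498 to 1085 between the hemispheres with peptide. Array weights gave 1447 and 854 genes between the hemispheres without and with peptide, and 276 and 3210 for uninjured and injured LPS/HI against Vehicle. A fit to all 8 groups gave 1431 and 1432 between the hemispheres, and the ribosomal protein level as covariate 1640 and 2082, with 143 for uninjured LPS/HI against Vehicle. The block for the number gave 2032 and 894. Between the hemispheres without peptide it ended all 10 list calls with an estimated correlation, and it changed no call of a named gene or of a list at the preset correlation there. With the peptide the correlations of equal numbers were 0.438, 0.395, 0.556, 0.0035 and 0.0365 and not every array correlated best with its own number, although the sex markers agreed between the hemispheres for all 5 numbers. A pairing of these arrays stays open and was taken for the injury score alone, whose interval is given with and without it. The interaction of peptide and LPS called 0 genes in the fit to all 8 groups and 0 with the filter on low signal, which leaves Tex24 out. With the estimated correlation 42 of 143 list calls held. The mean correlation of peptide and LPS effects was -0.0898, and of peptide and injury effects 0.132, with the shared group split. Without Xist and the Y-linked genes the unsplit correlations were -0.279 and -0.243, and the split ones 0.0169 and 0.117. Apart from the Tex24 filter, the cause was not tested. For LPS against Vehicle with Xist as covariate, the errors widened over the set of called genes, while their median change did not shrink.

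Leaving out 1 array at a time gave 137 to 175 genes for LPS against Vehicle, 203 to 286 for LPS with IDR against IDR, 285 to 641 between the hemispheres and 230 to 515 with peptide. It gave 51 to 95 for uninjured and 964 to 1798 for injured LPS/HI against Vehicle, 0 to 2 for the interaction of peptide and LPS, and 0 in each comparison of the peptide. The mean log2 fold change of cerebellum markers, peptide against no peptide in injured hemispheres, ranged from -0.153 to 0.0287 and turned positive without LPS/HI injured replicate 5, the array with high Gabra6. Both arrays numbered 3 of LPS/HI left out gave 558, 93 and 1793 genes for injured against uninjured, uninjured against Vehicle and injured against Vehicle.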

Other observations

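The comparison of uninjured LPS/HI hemispheres with LPS alone, and the interval without pairs, were chosen after seeing the data. Both tests of a response score were set beforehand.

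Uninjured LPS/HI hemispheres differ from the LPS group in the time since LPS, in the HI that the pups underwent and in the tissue, 1 hemisphere against brain. Their pups also received vehicle before LPS, which the label of the LPS group does not mention. Among the lower genes were Iigp1 at 5.39 ± 0.18 against 7.42 ± 0.37 (log2 fold change -2.03 ± 0.15, limma adjusted p = 6.86e-05, n = 5 each), Gbp4 at -1.84 ± 0.22, Gbp5 at -1.65 ± 0.14 and Irgm1 at -1.10 ± 0.15. Tnfsf10, a death ligand gene, was at -0.96, Tekt4 at -0.81 and Tgm2 (transglutaminase 2) at -0.66. Glucocorticoid response genes fell in 3 of 12 cases, Fkbp5 at -0.54, Map3k6 at -0.41 and Pdk4 at -0.41 (camera adjusted p = 5.44e-12, and 0.0144 with an estimated correlation). Hypoxia response genes shifted downward with none called (7.73e-05, and 0.0233 with an estimated correlation). The 5 genes that were higher were Pld4 at 0.81 ± 0.09, Lgals3bp at 0.69, Adgre5 at 0.67, Ctss at 0.63 and Myo1f at 0.44. Microglia markers shifted upward (1.51e-15, and adjusted p = 0.053 with an estimated correlation), and interferon response genes downward (2.57e-15, and adjusted p = 0.053 with an estimated correlation). limma called 27 genes, 5 higher and 22 lower, and 848 had an unadjusted p under 0.05 against 997 expected. Other splits of these 10 arrays called up to 3821 genes, so chance could not be excluded for the count, and such splits point to a structure of the samples.

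A lowering of the LPS response by the peptide was tested with a score, the mean signed level of 576 genes that changed with LPS over both peptide states, and the response was 0.38 without and 0.44 with the peptide, a difference of 0.06 ± 0.03 or 15.8% of the response (95% interval -3.51% to 35.1%, exact two-sided permutation p = 0.136). For 2674 injury genes the response of the injured hemisphere was 0.27 without and 0.28 with the peptide, a difference of 1.79% (95% interval -19.2% to 22.8%, exact two-sided permutation p = 0.857, with hemispheres taken as pairs by number, and -18.3% to 21.9% without pairs). The bound set in advance took a score equal or higher with the peptide, or any p of 0.05 or more, as evidence against a lowering, and the part on p was dropped after the values were seen because such a p does not show that values did not differ. Both scores were higher with the peptide, so both meet the part of the bound that remains. Both intervals run from negative to positive values, so this direction alone does not decide whether the peptide lowers a response. For LPS the interval leaves room for a lowering of up to 3.51%, and for injury for a larger one, so a lowering stays open for both. The arrays of LPS with IDR and of LPS alone also differed in Xist and in ribosomal protein level, as described above.

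Other splits of the same arrays, 100 per comparison, were used to ask whether chance can be excluded. It can for LPS with IDR against IDR (294 genes, highest other 3), uninjured LPS/HI against Vehicle (87, highest other 6) and injured LPS/HI against Vehicle (1663, highest other 1). Between the hemispheres without peptide (596 genes) and with it (498), 1 other of the splits in each called more, 1556 and 927, which points to a structure of the samples. These splits do not keep the hemispheres as pairs, so they do not decide about chance there. Of the 16 splits that part all 5 pairs of hemispheres without peptide, the others called 0 genes with limma, where the real one called 596 and had 2992 genes at an unadjusted p under 0.05. With 16 splits no share can fall under 0.05, so they cannot exclude chance by themselves. Such splits were not run with the peptide. For the interaction of peptide and LPS the real assignment and 2 others, 3 of 100, called 1 gene. In the comparisons of the peptide the count was 0, which all 100 splits reach whatever the data, so these splits decide nothing about chance. The highest other splits there called 1 gene for IDR against Vehicle, 2 for LPS with IDR against LPS, 3229 in injured and 2868 in uninjured hemispheres and 1 for the interaction with injury. Splits with as many as 3229 genes in the hemispheres point to a structure of the samples that the groups do not follow.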
